A study of Pseudomonas fluorescens Pf0-1 with 4 samples.

How the data were processed

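Total RNA of 4 shaken cultures of *Pseudomonas fluorescens* Pf0-1, a soil and rhizosphere bacterium, was measured on 4 single-colour NimbleGen expression arrays, 1 per culture. There were 2 cultures of the wild type and 2 of a mutant lacking the pstSCAB operon, which encodes the high-affinity phosphate transporter. Per the labels' protocols, cells were moved from an overnight LB culture into 5 mL of K10T-1 medium, harvested at an optical density of 0.6 and mixed directly with an RNA stabiliser, and the RNA was labelled with Cy3. The labels describe the replicates as separate cultures.

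Per the file headers, the authors' scanner files were written by NimbleScan version 2.3.78. Each deposited file gives the intensity of 389307 spots on a linear scale, before any background was taken off. Of these, 343332 spots carry 114444 probes in 3 blocks of 114444 spots each, so that every probe has 3 copies spread over the array, and 45975 spots carry random control sequences. The probes belong to 5733 features; 5711 of them have 20 probes and 22 have fewer, down to 1 probe. The mismatch column held 0 in every spot and was not used. The authors also deposited a table of 5733 features by 4 arrays, whose whole-number intensity values lie on a linear scale. The submitters' processing notes name RMA, and no further step is given in the sources used here. Its column medians were 130 and 139 for wild-type arrays 1 and 2, and 144 and 130 for mutant arrays 1 and 2. After log2 transformation its values correlated across features with those computed here at r from 0.993 to 0.994 on the same array, so its scale and direction were taken as unlogged intensity. These values were used only as an alternative.

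Spot intensities were background-corrected with normexp (offset 50), log2-transformed and quantile-normalized between arrays with all spots included (limma 3.58.1 in R 4.3.3). The 3 copies of a probe were averaged, and the probes of each feature were summarised by median polish. An offset of 50 shrinks log2 differences of dim features. Quantile normalization assumes that the 4 arrays share 1 distribution of signal. Random control spots entered the background and quantile steps but no feature value. A feature was called above background on an array when its value exceeded the 95th percentile of that array's random control spots, a limit of 8.27 and 8.09 log2 units on the wild-type arrays and 7.81 and 8.32 on the mutant arrays. Single spots spread more than a feature's summary of many spots, so this limit is strict. Limits from groups of 60 random spots lay lower, at 7.50 and 7.37 on the wild-type arrays and 7.21 and 7.51 on the mutant arrays. The groups went through the same averaging and median polish, but unrelated spots stood in for the 3 copies of a probe. A group can thus average over more sequences than a feature does, so these limits may be too low. Where a feature was under the limit on every array of a strain, its fold is given as a lower bound, from the bright strain's mean over the mean limit of the dim strain's arrays. Spots at the scanner's ceiling numbered from 50 to 227 per array and were kept.

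Mutant and wild type were compared with limma (lmFit and eBayes) on the feature values of all 4 arrays, with Benjamini-Hochberg adjustment over 5733 features and a threshold of 0.05. A second count required a change of at least 2-fold. The method was tested on simulated data of 5733 features, with 2 arrays per strain and 200 features changed by known amounts. It recovered 42.0% of the features changed by 0.5 log2 units. The share was 98.0% at 1 or 2 units and 100% at 3 units, and 3.43% of its calls were false. The simulated noise was normal, independent between features and drawn from limma's own fitted variances, with 1 variance for both strains. In the data the replicate difference had an SD of 0.26 log2 units in the mutant against 0.13 in the wild type. Neighbouring features also changed together. These rates therefore describe the method under its own assumptions, not in these data. With 2 cultures per strain the number of arrays limits the precision, and an exact permutation test of a single feature has only 3 distinct splits.

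The features carry the array design's own IDs. The files do not pair these IDs with gene names, and the gene table at hand belongs to another strain of the species, in which 0 of the 5733 IDs were found. Genes are therefore not named, and no genome of Pf0-1 was used here. The planned tests of fixed gene lists (Pho regulon, cyclic di-GMP, adhesin, motility, iron uptake and others), the check of the deleted pst genes and the search for PHO boxes could not be run, because no feature could be assigned to a gene. The rule for naming, fixed before the data were examined, was the largest increases and decreases among features past the threshold whose mutant arrays both lay on the same side of both wild-type arrays. It was shortened to 2 features in each direction, since an unpaired ID tells a reader little. The run of 5 features described by its first ID was chosen after its values were seen.

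The alternatives fixed before the data were examined were no background correction, normexp with offset 0, median scaling, cyclic loess, the mean over probes, the authors' values, a filter on dim features, each of the 3 copies alone, a trended and robust variance, leaving out each array, and the replicate number as a block. Leaving out saturated probes and the background limits from groups of random spots were added after the data were seen. The header lines named a separate image for each array and no batch that held more than 1 array, so no slide block was fitted.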

Results

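Gene expression was compared between wild-type *P. fluorescens* Pf0-1 and a mutant lacking the pstSCAB phosphate transporter operon, with 2 independent cultures per strain, 1 array per culture and 5733 features per array. According to the labels, the wild type represses the Pho regulon, the set of genes bacteria induce for phosphate acquisition, when phosphate is plentiful, and the mutant expresses it at any phosphate level. The comparison therefore asks which features differ in RNA level when that control is lost. The features are reported by their array IDs, because the files do not pair them with genes; for the same reason the features of the deleted genes could not be looked up, and the strain labels were not checked against them. Their positions in the genome are likewise not given.

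The median gene spot was 1.40 and 1.30 times as bright as the median random control spot on wild-type arrays 1 and 2, and 1.69 and 1.36 times on mutant arrays 1 and 2. Of the 5733 features, 2668 and 3125 were above background on the wild-type arrays and 3890 and 2552 on the mutant arrays. Across features, the 2 wild-type arrays correlated at r = 0.996 and the 2 mutant arrays at r = 0.984, whereas arrays of different strains correlated at r from 0.949 to 0.968. Only 1 feature differed by 2-fold or more between the wild-type arrays, against 33 between the mutant arrays and from 112 to 192 between arrays of different strains. The first principal component held 80.9% of the variance and separated the strains.

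Deletion of pstSCAB went with a rise of 193 features and a fall of 148, together 5.95% of those measured (limma, Benjamini-Hochberg adjusted p under 0.05). By at least 2-fold, 66 features rose and 59 fell, and by at least 8-fold, 10 rose and 4 fell. The counts at 2-fold were 36 and 51 without wild-type array 1, 34 and 44 without wild-type array 2, 95 and 90 without mutant array 2, and 42 and 37 without background correction. Of the 66 features that rose at least 2-fold, 45 were not above background on either wild-type array; of all 193 that rose, 77 were above it on neither and 102 on both. Of the 59 features that fell at least 2-fold, 41 were above background on both mutant arrays and 4 on neither; of all 148 that fell, 88 were above it on both and 19 on neither. These counts depended on the background limit: with lower limits, from groups of random spots, 8 of the 66 were above background on neither wild-type array and 58 of the 59 were above it on both mutant arrays. In all 341 called features both mutant arrays lay on the same side of both wild-type arrays, which passing the test all but requires. The same separation held for 42.8% of all features, where chance gives 33.3%. At an unadjusted p under 0.05, limma gave 834 features, where 287 would be expected by chance. The counts depended on which arrays entered the fit. The difference between replicate arrays had an SD over features of 0.13 log2 units in the wild type and 0.26 in the mutant. The counts fell to 37 higher and 57 lower without wild-type array 1, and to 35 and 46 without wild-type array 2. They were larger, 262 and 268, without mutant array 1, and 536 and 384 without mutant array 2, fits in which the spread comes from the wild-type pair alone. With median scaling in place of quantile normalization, 1 feature was higher and 1 lower. All 341 features kept their direction, which another scaling of the same spots could hardly turn.

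**Figure D1:**
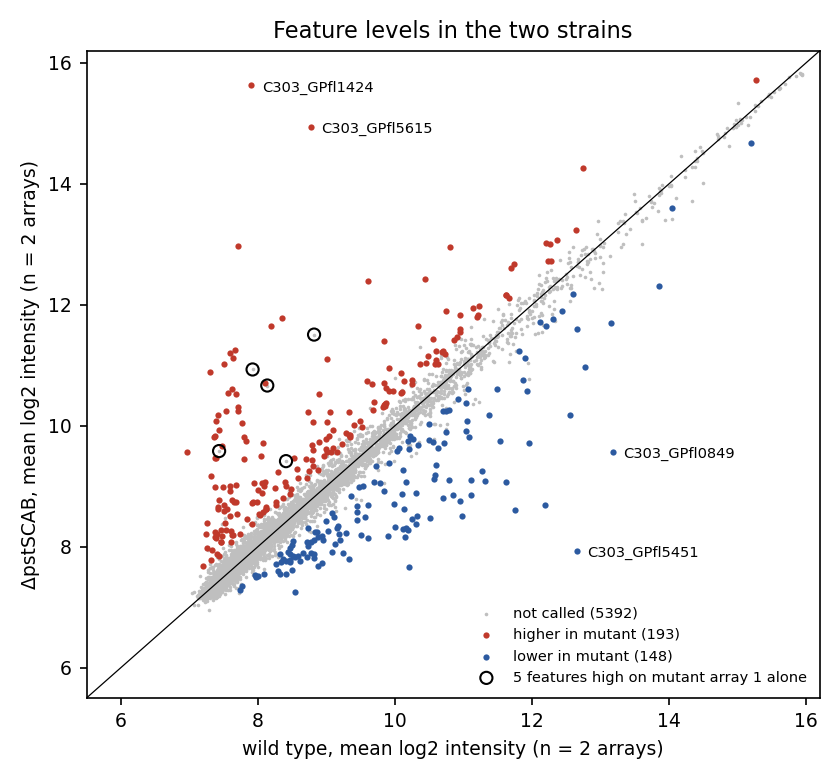
Mean log2 intensity of each feature in the mutant (vertical axis, n = 2 arrays) against the wild type (horizontal axis, n = 2 arrays), with the line of equal levels. Red points are the 193 features that rose and blue points the 148 that fell, many red points start near the wild-type floor, and circles mark 5 features that were high on mutant array 1 alone.

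The 2 largest rises were those of C303_GPfl1424 and C303_GPfl5615. C303_GPfl1424 stood at 7.90 ± 0.11 log2 units in the wild type (SD, n = 2), not above background on either array, and at 15.63 ± 0.14 in the mutant, at least 175-fold higher with this processing (limma adjusted p = 3.9e-08). With the limits from groups of random spots it was above background on both wild-type arrays, and the fold was 211. Leaving out probes saturated on any array raised its log2 difference from 7.72 to 7.81. Spots at the scanner's ceiling may have held this fold down, but the set of probes also changed, and the effects were not separated. C303_GPfl5615 rose 72.2-fold, from 8.77 ± 0.06 to 14.95 ± 0.15 log2 units (SD, n = 2; limma log2 difference 6.17, SE 0.10, adjusted p = 8.2e-08). The size of both rises depended on the processing. The lower bound for C303_GPfl1424 was 102-fold without background correction, 162-fold with median scaling and 210-fold with an offset of 0. Over 17 alternatives the log2 difference of C303_GPfl5615 ran from 5.42 without background correction to 6.84 from the authors' values. All 20 probes of the first and 19 of the 20 probes of the second were higher in the mutant. In the authors' deposited table these features read 87 and 106 on the wild-type arrays against 54975 and 46715 on the mutant arrays for C303_GPfl1424, and 274 and 263 against 33623 and 28167 for C303_GPfl5615.

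The largest falls started from bright features. C303_GPfl5451 fell from 12.65 ± 0.02 to 7.93 ± 0.11 log2 units (SD, n = 2; limma log2 difference -4.72, SE 0.09, adjusted p = 1.9e-07), and was above background on mutant array 1 but not on mutant array 2, so its level in the mutant lay near the background limit; with the limits from groups of random spots it was above background on both. C303_GPfl0849 fell 12.2-fold, from 13.18 ± 0.07 to 9.57 ± 0.04 log2 units (SD, n = 2; limma log2 difference -3.61, SE 0.09, adjusted p = 7.0e-07), and stayed above background on both. All 20 probes of each were lower in the mutant. The fall of C303_GPfl5451 was uneven along the feature. Its first 17 probes by position had a median difference of -4.94 log2 units and the remaining probes -1.15. This step of 3.79 log2 units was the largest of any feature, against at most 1.49 between the wild-type arrays and 2.03 between the mutant arrays. The split of each feature was the one that gave its largest step. Probes already dim in the wild type cannot fall as far, and the brightness of single probes was not examined. Over the alternatives the log2 difference ran from -5.83 to -3.83 for C303_GPfl5451 and from -4.04 to -3.25 for C303_GPfl0849, with the smallest fall of each without background correction and the largest from the authors' values. Under median scaling the differences of C303_GPfl5615 and C303_GPfl0849, 6.16 and -3.58 log2 units, no longer passed (limma adjusted p = 0.077 for each).

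**Figure D2:**
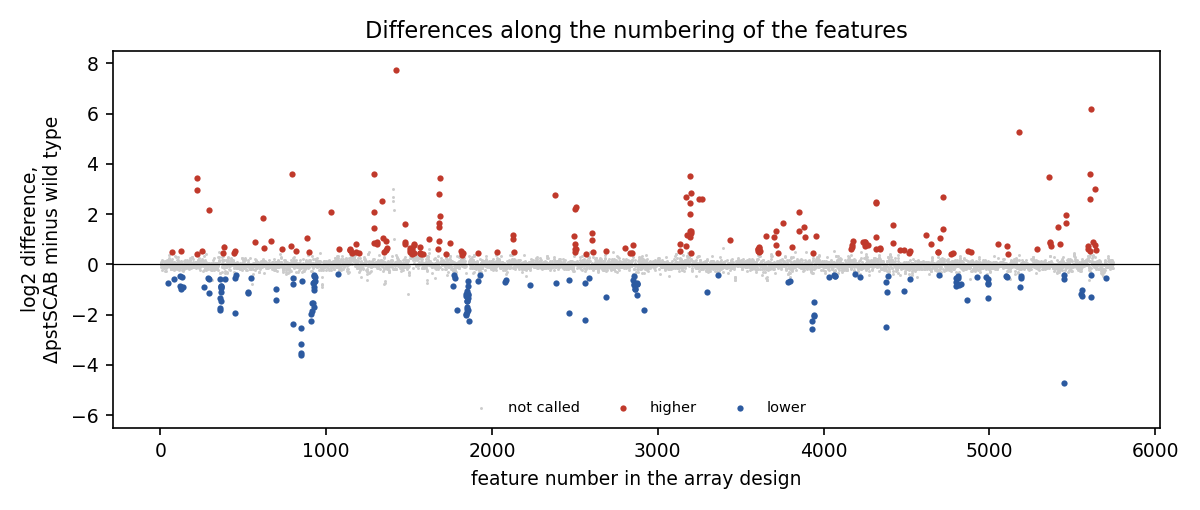
Log2 difference between mutant and wild type (vertical axis) for each of the 5733 features in the order of the array's numbering (horizontal axis). Red points rose and blue points fell, and many of them stand in vertical stacks of neighbouring numbers.

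A further 6 features differed by at least 2-fold between the strain means without passing the test. For 5 of them, a run of consecutive numbers that starts at C303_GPfl1404, the difference came from mutant array 1 alone. There they read from 10.64 to 14.21 log2 units, against 7.43 to 8.82 on the other 3 arrays. C303_GPfl1404 itself read 14.10 log2 units on mutant array 1, 7.76 on mutant array 2, and 7.89 and 7.95 on the wild-type arrays (limma adjusted p = 0.50). No difference between the strains is reported for them.

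**Figure D3:**
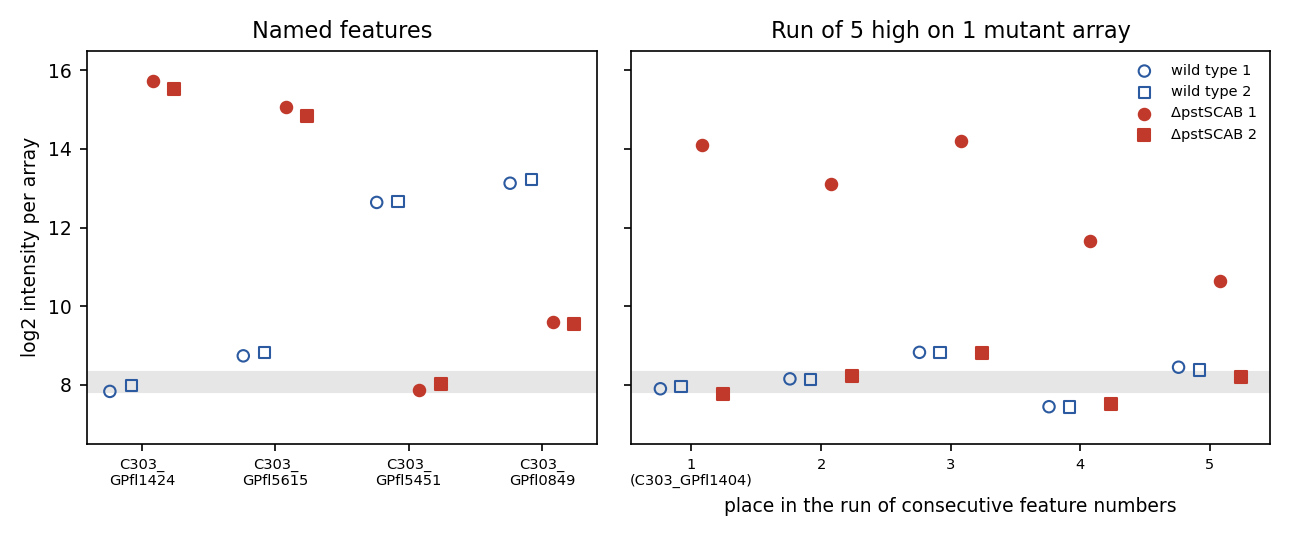
Log2 intensity on each array (vertical axis) of the 4 named features (left) and of the run of 5 features that starts at C303_GPfl1404 (right); blue open symbols are wild-type arrays, red filled symbols mutant arrays, and the grey band spans the background limits of the arrays, 7.81 to 8.32. The named features separate the strains on both arrays of each, and in the run only mutant array 1 stands apart.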

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

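The direction of all 341 called features was the same under each of the 10 alternatives that recomputed the feature values. These 10 start from the same arrays on which the 341 were chosen, so a turn was unlikely and its absence says little. The other 7 use the same values and, by construction, could not turn one. The limits from groups of random spots left the calls as they were. They moved the rises of at least 2-fold above background on neither wild-type array from 45 to 8. Other than the array left out, the counts of called features moved by more than 1.5 times under 2 alternatives. With median scaling, 1 feature was higher and 1 lower, and 1 each by at least 2-fold. An unadjusted p under 0.05 was then found for 277 features, where 287 would be expected by chance, and 231 of them were among the 341. The replicate difference of the mutant arrays then had an SD of 0.43 log2 units over features, against 0.26 with quantile normalization, and the median standard error was 0.17 against 0.10. Without background correction, which leaves a constant in every signal, 42 features were higher and 37 lower by at least 2-fold. Leaving out 1 array in turn gave 35 to 536 features higher and 46 to 384 lower, and 34 to 95 higher and 44 to 90 lower by at least 2-fold; without a mutant array, the lone one is assumed to vary like the wild-type pair. The authors' values gave 189 higher and 157 lower, of which 175 and 132 were also called from the scanner files. Same-numbered wild-type and mutant arrays did not deviate together (r = -0.05 across features), so the numbers were not treated as pairs; a replicate block gave 245 higher and 182 lower. No setting moved the median difference of all features by 0.1 log2 units, which the normalization between arrays all but fixes in advance. Of 68 results for the 4 named features, 66 still passed; the exceptions, both under median scaling, are given with the features, as are the ranges of their differences or bounds. No slide block was fitted, and the alternatives planned for the gene lists, the deleted genes and the PHO boxes were not run, since no feature could be assigned to a gene. From 44.5% to 67.9% of features were above background on an array, and from 85.1% to 96.4% with the limits from groups of random spots, so changes among dim features are limited by signal.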

Other observations

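All tests in this part were chosen after the data were seen. Changed features lay next to one another in the array's numbering. Of the 341 called features, 204 stood in 63 runs of 2 or more consecutive features called in the same direction, 141 neighbouring pairs in all, against at most 21 pairs in 1000 shuffled orders. Neighbours called in opposite directions made 4 pairs. The longest run of falls held 17 features, with differences from -2.25 to -0.65 log2 units, and the longest run of rises held 10, with differences from 0.47 to 3.51. Further runs of falls held 10 and 9 features. C303_GPfl0849 belonged to a run of 5 falls with a mean of -2.69 log2 units. Wild-type levels of neighbours also correlated (r = 0.58 across features, which are not independent replicates), so the numbering may follow gene order, with runs that are co-transcribed; no genome was used to test this.

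On mutant array 1 alone, 19 features were at least 2-fold lower than on the other 3 arrays, 18 of them beside another of the 19, and on mutant array 2 alone there were 0.

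The run of 5 features that starts at C303_GPfl1404 was high on mutant array 1 alone. A blemish on the array is argued against, since the smallest gap in any of the 3 blocks was 2.12 log2 units, and 97 of the 100 probes, spread over the array, were at least 2-fold higher there. RNA of other cells of these strains in the sample is argued against by the rises alone. On that array alone, 0 other features were at least 2-fold higher. The features on either side of the run had gaps of -0.17 and -0.35 log2 units. That count took only features whose values on the other 3 arrays lay within 0.5 log2 units. It left out falls, and 19 features were at least 2-fold lower on that array alone. A change in that culture, in expression or in copy number, and nucleic acid that carries this run alone stay open. With 1 array of that culture, no biological explanation was tested.

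The rises were smaller in mutant culture 2. The change in culture 2 was divided by that in culture 1 for the 66 features that rose at least 2-fold. The median ratio was 0.78 on the log2 scale (95% bootstrap interval over features 0.74 to 0.81). Of the 66, 64 rose more in culture 1. Features that change together are not independent, so the intervals given here are too narrow, and they measure no variation between cultures. Array-wide compression would shrink the falls alike, but their median ratio was 1.01 (0.95 to 1.03) over the 59 features that fell at least 2-fold. The ratio of the median changes was 0.88 (0.81 to 1.02) for falls and 0.71 (0.65 to 0.80) for rises, intervals that barely separated. By setting, the median ratio ranged from 0.55 to 0.81 for rises and from 0.85 to 1.13 for falls, with the lowest fall ratio under cyclic loess. Compression is thus argued against only for the called falls, in which both cultures agreed. The 19 features at least 2-fold lower on mutant array 1 alone, against 0 on mutant array 2 alone, go the other way. Wild-type RNA mixed into the sample would have to reach at least 31.0% to give the gap. That figure leaves out the wild-type signal the mix adds to risen features, so the share needed is larger. Yet 25 of the 59 fallen features lay under 31.0% of their wild-type level in culture 2. A difference between the cultures in how far they were induced stays open and was not tested. The arrays themselves also differed. The median gene spot was 1.69 times as bright as the median random control spot on mutant array 1 and 1.36 times on mutant array 2. Features above background numbered 3890 and 2552. With 1 array each, the quality of the array and the induction of the culture cannot be told apart.

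The 4 features numbered directly below C303_GPfl5615 were dim in the mutant. By the limits from single random spots, none of the 4 was above background on a mutant array and 1 was on the wild-type arrays, and by those from groups of random spots 3 were on 1 mutant array, 0 on both and 3 on both wild-type arrays, so no size is given for their differences; 2 of the 4 passed the test as lower. Their probes had a median rank at the 57th and 51st percentile of the random control spots on mutant arrays 1 and 2, against the 79th and 82nd percentile on the wild-type arrays, and 4 of the 5730 windows of 4 neighbours had a lower mean mutant level. These 4 features may be absent from the mutant, as the deleted operon of 4 genes would be, which is a hypothesis from these same arrays. A test with the group limits found 0 windows of 4 neighbours at the random control level on both mutant arrays and below both wild-type arrays. The hypothesis called for at least 1 such window, and that was not met. Among the 4, 2 features read 7.22 and 7.32 on mutant array 1 (limit 7.21), and 1 read 7.59 on mutant array 2 (limit 7.51). Without cross-hybridisation the limits would pass 66.3% of truly absent runs, if the 8 values were independent and absent features spread like the random groups. Neither assumption was tested, and the same probes sit on both mutant arrays. That figure therefore does not tell whether a miss on 3 features is unusual. The test cannot decide, because the group limits may be too low and the random controls do not cover cross-hybridisation to real probes. No gene name was at hand.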
